A study of Mus musculus with 6 samples.

How the data were processed

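Total RNA of cultured mouse prostate epithelial cells was measured on 6 one-colour Affymetrix arrays, 3 from Ccnd1+/+ cells and 3 from Ccnd1-/- cells, all of the FvB strain according to the labels. Per the labels' protocols, RNA was extracted with Trizol and copied into biotin-labelled cRNA, and the cells grew in F-12 medium with serum, insulin, EGF, hydrocortisone, transferrin and pituitary extract, with no specific treatment. The design text calls both groups Ccnd1+/+, while the title and the genotype of each sample name 3 arrays as Ccnd1-/-; groups were taken from the samples' own titles. The deposited values are log2 expression values, 1 per probe set and array, and RMA (background correction, normalization between arrays and summary of probes) is the method named in the submitters' processing notes; its version and software are not given in the sources used here. The values ran from 1.48 to 14.2 and the array medians from 4.96 to 5.02. An array has no read depth, so the number of arrays, 3 per group, limits the precision. No detection calls were used here. Nothing in the labels says that the 3 samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

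Of 45101 probe sets, 34945 named 1 gene in the platform annotation used here, 932 named several genes, 9160 named none and 64 were hybridisation or quality controls. Symbols were compared with the RefSeq genes of assembly GRCm38.p6 through the gene identifier, which matched 34741 probe sets and changed 0 symbols. Each gene was represented by the probe set with the highest mean over all 6 arrays, which gave 18193 genes, 9010 of them with several probe sets. Probe sets naming several genes or none stayed out of gene counts. Leaving the control probe sets out was decided after a first fit.

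Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided, 2 groups, no covariate), with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05. Differences are log2 Ccnd1-/- minus Ccnd1+/+, with the moderated standard error (SE); group means carry the SD of 3 arrays. The 26 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists, which compares a list with all other genes; camera with an estimated correlation and fry were run beside it. The lists covered G1 cyclins, CDKs and inhibitors; DNA replication; mitosis; homologous recombination and Fanconi anaemia; non-homologous end joining; DNA damage sensing and checkpoint; excision and mismatch repair; p53 targets; androgen-responsive genes; oxidative phosphorylation; glycolysis; cholesterol synthesis; interferon response; NF-kB and inflammatory cytokines; the Notch pathway; extracellular matrix; genes next to Ccnd1; and markers of luminal and basal epithelium, fibroblasts, smooth muscle, endothelium, leukocytes, adipocytes, neuroendocrine cells and seminal vesicle secretion. Of the 656 genes on these lists, 45 had no probe set naming only them in the annotation used and were not analysed here. A further 7 lists, adjusted as a family of their own, were written after the results had been seen. They held macrophage genes, T and B lymphocytes, Schwann cells and glia, noncoding RNA listed as nuclear-retained, immediate early genes, ribosomal proteins, and the aryl hydrocarbon receptor with its targets.

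Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named were Ccnd1; the 12 genes with the largest positive and the 12 with the largest negative difference among genes past the threshold whose groups did not overlap and whose brighter group lay above the median of all probe sets (4.99), passing over clone or model names (1 among the higher genes); the 4 members of each list with the smallest p-value; and the other D-type cyclins, Cdk4, Cdk6 and the neighbours of Ccnd1 past the threshold. Alternatives were the mean of a gene's probe sets, every probe set on its own, only genes above the median, a second quantile normalization, centring of each array, a trended and robust prior, array weights, the replicate number as a block, and leaving out each array. A covariate made from the 3' minus 5' difference of the Gapdh and actin control probe sets was added after the data had been seen. The limma and camera steps were tested on simulated data: with the arrays' own spread and 18193 genes, 85% of 100 genes changed by 1 log2 unit and 38% of 100 changed by 0.5 were called, 8.21% of the calls were false, and 1 list shifted by -0.4 was called while 0 of the others were. Genes were drawn independently, so the simulation does not test camera where genes of a list are correlated.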

Results

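Gene expression was compared between cultured mouse prostate epithelial cells that carry Ccnd1, the gene of the G1 cyclin D1, and cells homozygous for its disruption, with 3 arrays per genotype. The series concerns the part of cyclin D1 in sensing and repairing DNA damage under androgens, and the arrays address which transcripts differ when the gene is lost. The labels name no androgen treatment. Arrays of the same genotype correlated at r = 0.9952 to 0.9977 across probe sets and arrays of different genotype at 0.9889 to 0.9932, where probe sets are not independent replicates. Readings of RNA quality differed with genotype: the 3' minus 5' difference of the actin control was 2.77 ± 0.04 log2 units (SD, n = 3) in Ccnd1+/+ and 2.38 ± 0.14 in Ccnd1-/- cells (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 arrays allow). The same difference for Gapdh was 2.75 ± 0.58 and 2.31 ± 0.13 (exact p = 0.2), with Ccnd1+/+ replicate 3 at 3.41, and the middle control probe set of 18S rRNA read 7.64 ± 0.91 and 8.79 ± 0.28 (exact p = 0.1).

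Ccnd1 transcript fell in all 3 Ccnd1-/- arrays. Its brightest probe set read 10.51 ± 0.08 in Ccnd1+/+ and 7.56 ± 0.23 in Ccnd1-/- cells (SD, n = 3), a log2 difference of -2.95 (SE 0.12, limma adjusted p = 1.54e-06), or 7.72-fold lower. The other two Ccnd1 probe sets differed by -2.52 and -1.30. The signals left in Ccnd1-/- cells still lay at the 64.8 to 81.4 percentile of all probe sets of those arrays. Which part of the gene was deleted, and whether the probes lie in it, is not given in the sources used here. Among the other D-type cyclins and their kinases, Ccnd2 rose from 11.68 ± 0.06 to 12.47 ± 0.11, or 1.73-fold (adjusted p = 0.00103). Ccnd3 differed by -0.04 (adjusted p = 0.86), and the partner kinase genes Cdk4 and Cdk6 by -0.09 (adjusted p = 0.744) and 0.19 (adjusted p = 0.3). None of these 3 passed the test, though Cdk6 did with the mean of its probe sets (0.31, adjusted p = 0.0236). The signs for Ccnd3 and Cdk4 turned without Ccnd1+/+ replicate 3 (0.05 and 0.09), and that of Ccnd3 also without Ccnd1-/- replicate 3 (0.04).

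**Figure D1:**
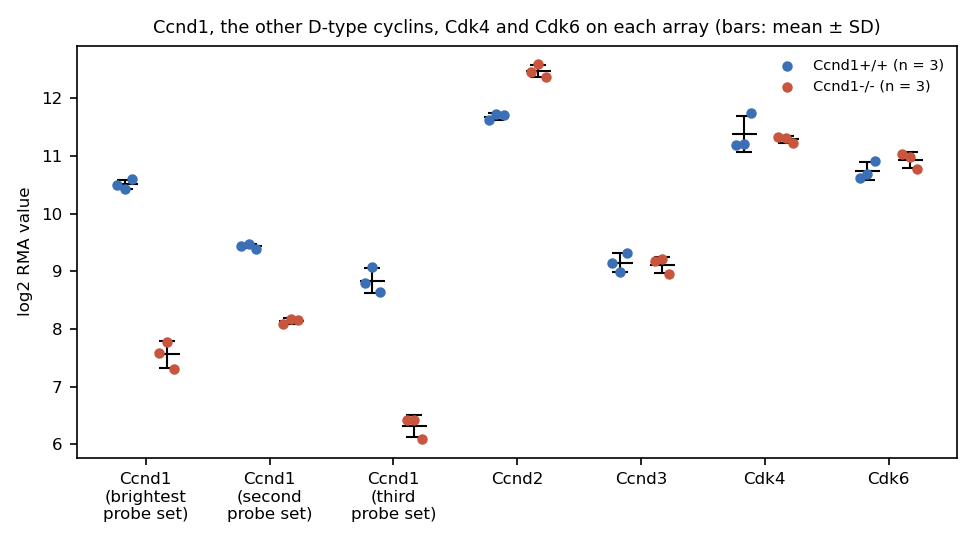
Log2 RMA values (y axis) of the 3 Ccnd1 probe sets, the other D-type cyclins, Cdk4 and Cdk6 (x axis) on each of the 3 Ccnd1+/+ arrays (blue) and 3 Ccnd1-/- arrays (red), with bars for mean ± SD. For the brightest Ccnd1 probe set the group means are 10.51 and 7.56, and for Ccnd2 they are 11.68 and 12.47.

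Across the genome, 1804 of 18193 genes (9.92%) passed the threshold, and most of them went down: 1355 were lower in Ccnd1-/- cells and 449 higher. In all 1804 the 3 arrays of one genotype lay beyond the 3 of the other, which was true of 32.5% of all genes where chance gives 10%. At least 2-fold changes were seen in 158 genes, 42 higher and 116 lower. The largest rise was in Gbp2b, which encodes an interferon-inducible guanylate-binding protein, from 2.74 ± 0.42 to 7.39 ± 0.19 (adjusted p = 1.54e-06), where the Ccnd1+/+ signal was as low as that of bacterial control probe sets, so the size of the rise is rough. It was followed by Cap1, an actin regulator (log2 difference 3.23, SE 0.50), Vapb, a membrane protein of the endoplasmic reticulum (2.88, SE 0.11), and Svs4, a seminal vesicle secretory protein (2.84, SE 0.36). Ergic1, Kcnq1ot1, Eml6, Igf2r, Zfp800, Psap, Pigt and Kdm5a rose by 1.52 to 1.72. Kcnq1ot1 is a nuclear noncoding RNA of an imprinted region, Psap encodes the lysosomal precursor prosaposin and Kdm5a a histone demethylase.

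The largest measured fall was in Fmod, the gene of the collagen-binding proteoglycan fibromodulin, from 6.24 ± 0.16 to 2.90 ± 0.18 (adjusted p = 1.54e-06). That signal, like those of Fabp7, Reln, Fgf5, Cdh19, Apol8 and Slc35f1 in Ccnd1-/- cells, was as low as that of bacterial control probe sets, so sizes and ranks of these falls are rough. Besides Ccnd1, the others were Fabp7 (log2 difference -2.73, SE 0.18), Reln (-2.71, SE 0.09), Fndc1 (-2.66, SE 0.11), Fgf5 (-2.60, SE 0.20), Cdh19 (-2.60, SE 0.18), Sfrp1 (-2.51, SE 0.26), Ngfr (-2.50, SE 0.10), Apol8 (-2.33, SE 0.11), Slc35f1 (-2.33, SE 0.14) and Lyz1 (-2.31, SE 0.10). Sfrp1 encodes a secreted antagonist of Wnt signalling, Ngfr the low-affinity neurotrophin receptor and Reln the extracellular glycoprotein reelin. Lyz1 and its near-identical neighbour Lyz2 can share probes, so their signals are not separate measurements.

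Some differences were larger in 1 probe set than in others of the gene: other probe sets of Vapb differed by 0.19 and 0.49, another of Igf2r by -0.22, the second brightest of Ergic1 by -0.08 while others of it rose by 0.90 and 1.26, and the 6 others of Zfp800 by -0.32 to 0.28. The others of Eml6 differed by 0.19 and -0.14 and the 5 others of Kcnq1ot1 by 0.01 to 0.39, and with the mean of its probe sets Kcnq1ot1 rose by 0.48. By that mean Zfp800 did not pass (0.20, adjusted p = 0.233). Among the falls, another probe set of Fndc1 differed by -0.19, of Fgf5 by -0.19, of Reln by -0.06 and of Slc35f1 by -0.07, and others of Ngfr by -0.80 and -0.18. Other probe sets of Lyz1 differed by -2.05 and, at a low mean signal of 2.50, by 0.006. By the same mean Fmod fell by 1.53, Reln by 1.39 and Ngfr by 1.16. With the 3' minus 5' difference of the controls as a covariate, 252 genes passed, 85 higher and 167 lower, and Cap1 (1.63), Svs4 (2.98), Kcnq1ot1 (0.97) and Zfp800 (1.54) no longer did. Leaving out 1 array gave 692 genes (without Ccnd1-/- replicate 1) to 1195, and 880 without Ccnd1+/+ replicate 1.

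**Figure D2:**
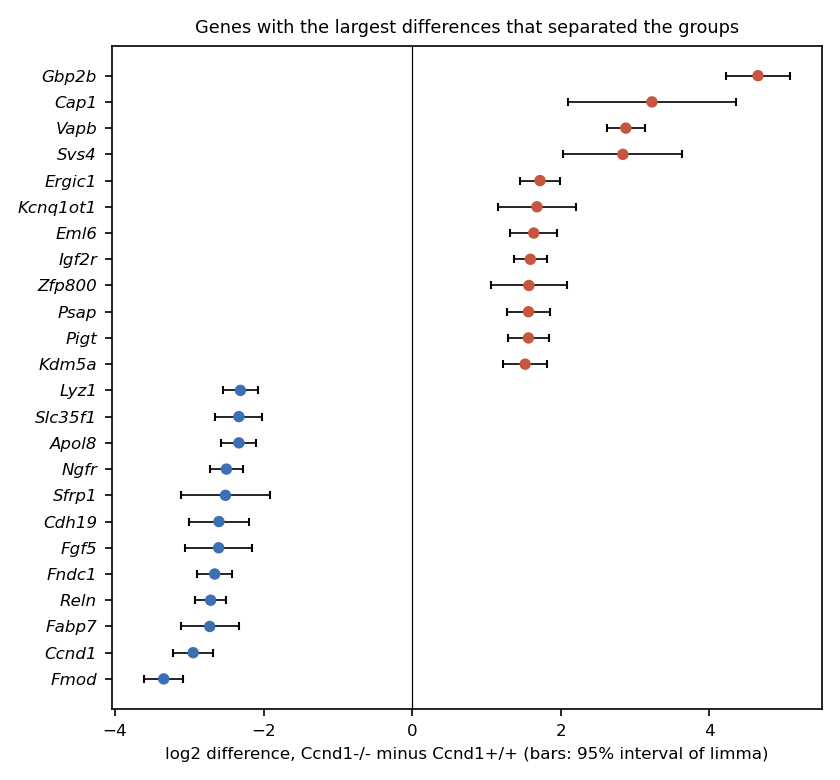
Log2 difference between Ccnd1-/- and Ccnd1+/+ cells (x axis) of Ccnd1 and the genes with the largest rises (red) and falls (blue) that passed the test with separated groups (y axis), each with limma's 95% interval. Differences run from -3.34 for Fmod to 4.66 for Gbp2b, and the interval of Cap1 is the widest.

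Some G1 genes rose and some fell, and most of the mitotic genes that passed were lower. Of 26 measured G1 cyclins, CDKs and inhibitors, 3 rose, 2 fell and 21 did not pass (adjusted over the list alone, 3 rose and 5 fell). Beside Ccnd2, the inhibitor gene Cdkn2a rose by 0.43 at a low signal (4.08 ± 0.04), a call lost without any 1 of 5 arrays and with the control-probe covariate, and the phosphatase gene Cdc25a, chosen after its values were seen, by 0.32, while the inhibitor genes Cdkn1c (7.44 ± 0.13 against 6.11 ± 0.46, log2 difference -1.33) and Cdkn2c (-0.41) fell. The list as a whole did not differ from other genes (camera adjusted p = 0.749). Of 37 DNA replication genes, 6 fell and 1 rose (list alone, 10 and 1): Dnmt1, the maintenance DNA methyltransferase, fell by 0.77, Gmnn, the gene of the licensing inhibitor geminin, by 0.40 and Pcna, the gene of the polymerase clamp, by 0.39, while Tyms rose by 0.47 at a low signal (3.26 ± 0.12). With the mean of its probe sets Tyms read 0.12 (adjusted p = 0.314). Without Ccnd1-/- replicate 1 the number of replication genes lower was 1, and Gmnn and Pcna were not among the genes past the threshold (adjusted p = 0.0723 and 0.0875). The replication list did not pass (adjusted p = 0.116), but did with the mean of a gene's probe sets (adjusted p = 0.0101, 10 lower).

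Of 37 mitotic genes, 8 fell and 1 rose (list alone, 12 and 1), 34 had a negative difference, and the list was lower as a group (mean -0.24, camera adjusted p = 0.00166; adjusted p = 0.681 with an estimated correlation). Ttk, a spindle checkpoint kinase gene, fell by 0.50, Cenpa, the gene of the centromeric histone, by 0.47 and Birc5, the gene of survivin, by 0.47, whereas Pttg1, the gene of the separase inhibitor securin, rose from 9.07 ± 0.05 to 9.81 ± 0.07. With the control-probe covariate the mitosis list no longer passed (adjusted p = 0.191), and without Ccnd1-/- replicate 1 the number of its members past the threshold and lower was 0.

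Few DNA repair and damage-sensing genes passed. Of 33 genes of homologous recombination and the Fanconi anaemia pathway, Rad52, which helps load the recombinase on DNA, rose from 6.90 ± 0.10 to 7.55 ± 0.05 (1.58-fold, adjusted p = 0.00241) and Mus81, a structure-specific endonuclease gene, fell by 0.39, as they did over the list alone. Fanca and Fancf differed by -0.33 and -0.30 without passing. Of 13 end-joining genes, 1 fell by either adjustment, the ligase cofactor gene Xrcc4 (-0.53, adjusted p = 0.0293). The related genes Aplf (-0.29), Nhej1 (-0.23) and Polm (-0.22) did not pass. Of 28 damage-sensing and checkpoint genes, H2ax, the gene of the histone variant phosphorylated at breaks, fell by 0.37 (adjusted p = 0.0282), and over the list alone 0 passed. Rnf8 (-0.26), Tipin (-0.27) and Mapkapk2 (0.27) did not. Of 30 excision and mismatch repair genes 0 passed by either adjustment in limma, with Pms2 (-0.28), Mpg (-0.28), Neil1 (-0.33) and Ung (-0.23) nearest. None of the 4 lists differed from other genes (camera adjusted p = 0.709 for the first and second, 0.732 for damage sensing and 0.803 for excision and mismatch repair). Rad52 passed in all 6 leave-outs but not with the control-probe covariate, where its difference was 0.62 (adjusted p = 0.0706) and those of Mus81, H2ax and Xrcc4, also lost, were -0.25, -0.25 and -0.21. Under all alternatives the difference of Rad52 ran from 0.35 to 0.71. Without the covariate Mus81 and H2ax lost their calls with a second quantile normalization (adjusted p = 0.0698 and 0.0563), with the replicate block (0.0762 and 0.0672), without Ccnd1+/+ replicate 2 or 3 (adjusted p up to 0.0899 and 0.0723) and without any 1 of the Ccnd1-/- replicates (up to 0.103 and 0.0902). Xrcc4 lost its call in the same 5 leave-outs only (adjusted p up to 0.0948).

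Targets of p53 went both ways: of 31, 3 rose and 5 fell (list alone, 3 and 6; camera adjusted p = 0.732). The stress-response gene Sesn2 rose by 0.58 and the translesion polymerase gene Polk by 0.64, while Plk2 (-0.63) and Trim32 (-0.50) fell. The mean and median of this list were below 0 (-0.04 and -0.02), while camera placed it above other genes, whose median was -0.06. Of 31 androgen-responsive genes, the transcription factor gene Maf rose by 0.62, and Srebf1, a regulator of lipid synthesis, fell by 0.53, the transporter gene Abcc4 by 0.48 and Mme by 0.48 at a low signal (2.99 ± 0.19). With the mean of its probe sets Maf read 0.13 (adjusted p = 0.369). The same 4 passed over the list alone, and the list did not pass (adjusted p = 0.709).

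Metabolic lists did not pass. Of 41 oxidative phosphorylation genes, Atp5g1 fell by 0.43 and Ndufs4 by 0.40, Uqcrq (-0.50) and Sdhd (-0.34) did not pass, and over the list alone 0 did (camera adjusted p = 0.749). The call of Atp5g1 was lost under 10 of 15 alternatives and that of Ndufs4 under 12, all 6 leave-outs among them. Of 17 glycolysis genes, Aldoc (-0.41) and Bnip3 (-0.37) fell, and 3 did over the list alone, with Pfkp at -0.35 and Pdk1 at -0.27 (adjusted p = 0.151). Aldoc lost its call under 4 of 15 alternatives and Bnip3 under 6, and leaving out 1 array left 0 to 3 glycolysis genes lower. Of 20 cholesterol synthesis genes, Pmvk fell by 0.63 and Dhcr7 by 0.44, by either adjustment, whereas the regulator gene Srebf2 (0.31) and the sterol transport gene Stard4 (0.30) did not pass (adjusted p = 0.169).

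Some matrix, interferon and cytokine genes fell in Ccnd1-/- cells. Of 32 interferon-response genes, 8 fell and 0 rose (list alone, 13 and 2), among them Rsad2 (-0.79), Cxcl10 (-0.63), Tap1 (-0.49) and Psmb8 (-0.46). Tap1 read -0.16 with the mean of its probe sets (adjusted p = 0.192), and Rsad2 and Psmb8 lost their calls under 5 and 6 of 15 alternatives. The list fell short of the threshold (mean -0.26, camera adjusted p = 0.052), and passed with array weights (adjusted p = 0.00663), with the replicate block (adjusted p = 0.0194) and without Ccnd1-/- replicate 3 (adjusted p = 1.64e-05, 13 members lower). It did not pass in the other leave-outs, with 1 member lower without Ccnd1-/- replicate 1 and a mean of -0.18 (adjusted p = 0.239) without Ccnd1-/- replicate 2. Gbp2b, which rose, was not on this list. Of 28 NF-kB and cytokine genes, 5 fell (list alone, 7): the acute-phase gene Saa3 from 8.68 ± 0.06 to 6.96 ± 0.52 (3.29-fold lower), the chemokine genes Cxcl2 (-0.85) and Cxcl1 (-0.35), Il1a (-0.47, at a low signal of 3.38 ± 0.12) and, chosen after its values were seen, Lif (-0.32). Cxcl1 lost its call under 10 of 15 alternatives and read -0.17 with the mean of its probe sets, and leaving out 1 array left 2 to 7 members lower. The list did not pass (adjusted p = 0.169). In the Notch pathway, with 23 genes, Notch1 rose by 0.56 and Notch4 (-0.98), Notch2 (-0.36) and Heyl (-0.41) fell, against 2 higher and 7 lower over the list alone (adjusted p = 0.713). Notch2 and Heyl each lost their call under 8 of 15 alternatives, and Notch2 read -0.09 with the mean of its probe sets (adjusted p = 0.569). Of 36 extracellular matrix genes, 14 fell and 0 rose (list alone, 15 and 1), and the list was lower as a group (mean -0.36, camera adjusted p = 0.00166; adjusted p = 0.666 with an estimated correlation). Fibrillar and beaded-filament collagens led it: Col1a1 fell from 11.14 ± 0.03 to 9.98 ± 0.21 (2.23-fold), Col3a1 by 1.09, Col6a3 by 1.19 and Col6a1 by 0.99. With the control-probe covariate the matrix list no longer passed (adjusted p = 0.249), and without Ccnd1+/+ replicate 3 the number lower was 6.

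Some markers of basal epithelium rose, and some of fibroblasts and leukocytes fell. Of 19 luminal markers, the tight junction gene Cldn4 rose by 0.44, and Cldn3 (-0.33), Spink1 (-0.38) and Psca (0.28) did not pass (list alone, 1 higher and 2 lower, mean -0.04 but above other genes in camera, adjusted p = 0.732). Cldn4 lost its call under 6 of 15 alternatives. Of 20 basal markers, 4 rose and 1 fell (list alone, 4 and 2): Col17a1 by 0.61, Fgfr2 by 0.45, Cdh3 by 0.44 and Krt5, the basal keratin gene, by 0.39, while Perp, chosen after its values were seen, fell by 0.46. The list was higher as a group (mean 0.10, adjusted p = 0.00247; adjusted p = 0.568 with an estimated correlation). Of 26 fibroblast markers, 10 fell and 0 rose (list alone, 15 and 0; mean -0.47, adjusted p = 5.12e-06; adjusted p = 0.568 with an estimated correlation), including Fap, a stromal peptidase gene, by 1.15 and Ogn by 0.69. This list shares 6 genes with the matrix list, 5 of them lower, among them Col1a1 and Col3a1. Of 24 leukocyte markers, 12 fell and 0 rose (list alone, 15 and 0; mean -0.63, adjusted p = 1.74e-06; adjusted p = 0.418 with an estimated correlation): lysozyme gene Lyz2 from 7.94 ± 0.02 to 5.78 ± 0.06 (4.48-fold), Ctss from 8.46 ± 0.10 to 6.37 ± 0.33 (4.25-fold), Tyrobp by 1.59 and the complement gene C1qa 2.83-fold. The 8 interferon, 5 cytokine and 14 matrix genes that passed as lower were lower in the same arrays as these markers, but so was every gene called lower. This does not tell whether their falls go with a change of cell types. In camera with the preset correlation the basal, fibroblast and leukocyte lists passed under all 15 alternatives of processing. The trended and robust prior does not enter camera, so that alternative could not change these calls. Leaving out 1 array left only 1 to 3 basal markers higher, and 5 to 12 fibroblast and 7 to 11 leukocyte markers lower. With the control-probe covariate these numbers were 0, 1 and 6, where the list means were 0.13, -0.42 and -0.64.

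No list of the remaining cell types passed. Of 14 smooth muscle markers Smtn fell by 0.50, and Des (-0.30), Rgs5 (-0.30) and Actg2 (-0.34) did not pass (adjusted p = 0.865). Of 17 endothelial markers Emcn fell 3.03-fold, from 5.30 ± 0.16 to a low signal of 3.70 ± 0.06, so the size is rough. Vwf (-0.60), Cdh5 (-0.50) and Tek (-0.25) did not pass. The endothelial list (mean -0.25, adjusted p = 0.151) passed with the mean of a gene's probe sets (adjusted p = 0.00816) and with every probe set on its own (adjusted p = 0.00146). Of 14 adipocyte markers the fatty acid receptor gene Cd36 was lower at a low signal in both groups (3.06 ± 0.37 and 2.15 ± 0.12), with Cebpa (0.24), Dgat2 (-0.22) and Plin4 (-0.16) not past the test (mean -0.08 but above other genes in camera, adjusted p = 0.749). Of 11 neuroendocrine markers Ncam1 fell by 0.47 and Chgb by 0.53, with Scg2 (-0.50) and Snap25 (-0.26) not past the test (adjusted p = 0.247). With the mean of its probe sets Ncam1 read -0.18 (adjusted p = 0.163), and Chgb lost its call under 4 of 14 alternatives. Over the smooth muscle, endothelial, adipocyte and neuroendocrine lists alone, 1, 1, 1 and 3 markers fell. Of 7 seminal vesicle genes, Svs4 and Svs5 rose and Pate4 was lower at a low signal in both groups (3.73 ± 0.42 and 2.64 ± 0.05), by either adjustment, with Svs3a at 0.19. The list (mean 0.50, camera adjusted p = 0.151) passed without Ccnd1-/- replicate 2 (adjusted p = 0.0125). It also passed with only genes above the median (adjusted p = 0.00441), but there it held only 2 members, Svs4 and Svs5 (mean 2.16). That pass therefore adds nothing to the rises of these 2 genes. Svs5 rose from 5.64 ± 0.16 to 7.14 ± 1.01, a call lost under 7 of 15 alternatives. Genes that neighbour Ccnd1 on chromosome 7 were lower in 2 of 11, Dhcr7 (-0.44) and Nadsyn1 (-0.40), by either adjustment. Ano1 (0.23) and Fadd (-0.25) did not pass. The list, with a mean of -0.07 and a median of 0.02, did not differ from other genes (adjusted p = 0.906).

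Of the 26 lists 5 passed with the preset correlation, mitosis, matrix, fibroblast and leukocyte lower and basal epithelium higher, and 0 with an estimated one (adjusted p = 0.418 to 0.914). By fry 11 passed as moving, on balance, one way, with matrix, fibroblast and leukocyte among them but not mitosis (adjusted p = 0.0735) or basal epithelium (adjusted p = 0.0929), and with homologous recombination and end joining, which camera did not call. When the 6 arrays were divided in the other 9 ways, each of these 5 lists passed in 2 or 3 of the divisions, and of the 88 named genes past the threshold beside Ccnd1, 35 lost their call when some 1 array was left out.

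**Figure D3:**
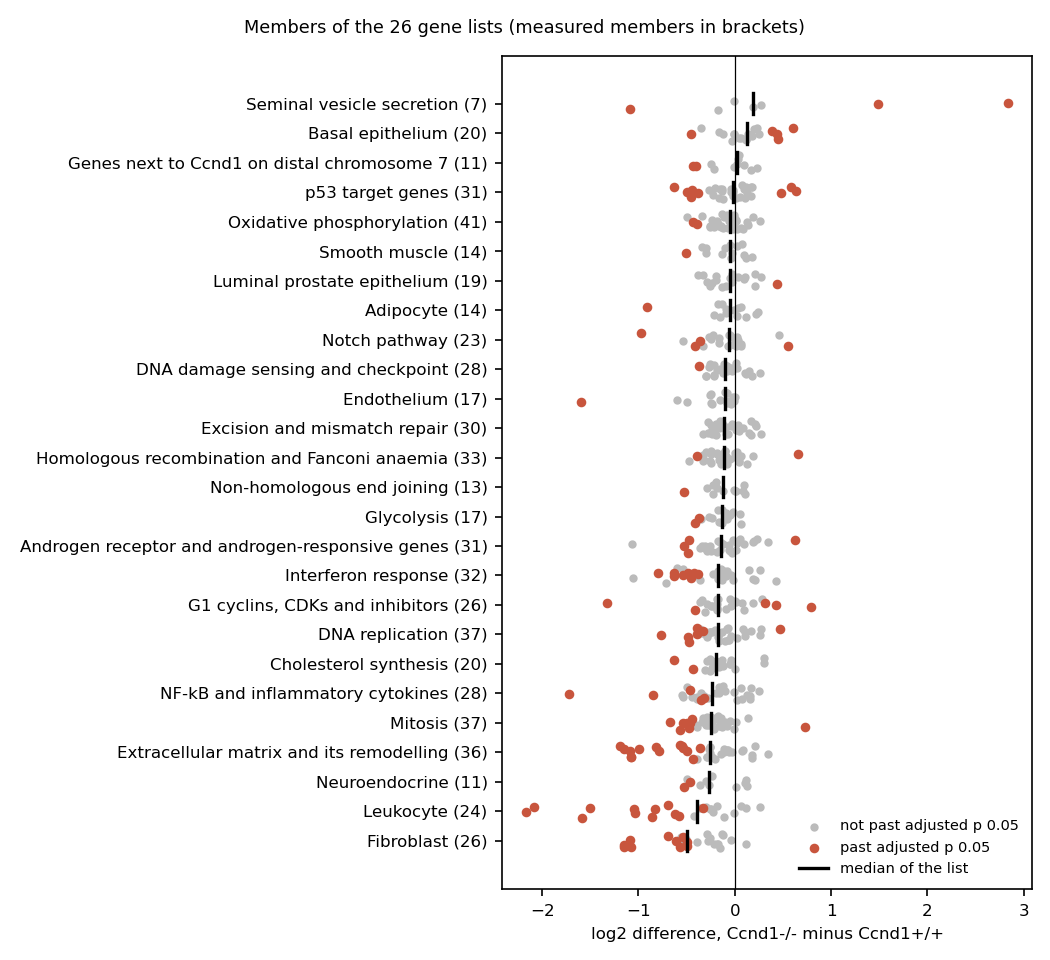
Log2 difference between Ccnd1-/- and Ccnd1+/+ cells (x axis) of every measured member of the 26 gene lists (y axis), red where the gene passed the adjusted threshold and grey where it did not, with a black bar at each list's median. The fibroblast and leukocyte lists lie lowest, with medians of -0.50 and -0.39.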

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

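The test of the control-probe covariate was chosen before its result was seen; the tests on other probe sets, macrophage genes, smooth muscle markers and neighbours of Ccnd1 were chosen after at least part of their values had been seen.

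Probe sets that name no gene took no part in the comparisons of genes, yet 984 of the 9160 were higher in Ccnd1-/- cells and 207 lower, or 10.7% against 4.71% higher among probe sets that name 1 gene. Of 64 control probe sets 5 were higher, those of the 5' end of 18S rRNA (by 1.19 log2 units) and of beta-actin (by 0.58), of the middle of beta-actin and of Gapdh, and MUR_b2, while those of the 5' end of pyruvate carboxylase and the transferrin receptor did not pass. With the 3' minus 5' difference of the controls as a covariate, the median rise of the 984 went from 0.64 (median SE 0.114) to 0.57 (0.163), a ratio of 0.887. Leaving out 1 array gave ratios of 0.859 to 1.11, the highest without Ccnd1+/+ replicate 3. Only 291 kept their call and 765 an unadjusted p under 0.05. The covariate ran from 2.54 to 3.10 on Ccnd1+/+ arrays, highest in replicate 3, and from 2.28 to 2.38 on Ccnd1-/- arrays. It separated the genotypes and varied within a group mainly through that replicate, so the ratio cannot decide whether it is the source. Of all 42 genes at least 2-fold higher, 25 had other probe sets whose mean lay above the median of all probe sets. Of these 43 probe sets, 18 (41.9%) were higher too. For the 116 genes at least 2-fold lower, 17 of 27 such probe sets (63.0%), from 21 genes, were lower (Fisher's exact test, two-sided, p = 0.14). The test counts several probe sets of 1 gene separately, though they are not independent. The other probe sets of the higher genes had a median of 0.31, where those chosen for the same genes had 1.44, and 2 were called lower. For the lower genes the medians were -1.03 and -1.26, and 0 were called higher. The sizes were thus less shared among the rises, while the counts did not differ by the test. Signal from part of a transcript, such as unspliced RNA, cannot be told apart from a change of the whole transcript with so few probe sets. The genotype and RNA quality, whether or not these controls read it, stay open.

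Leukocyte markers were lower. If Ccnd1-/- cultures held fewer macrophages, nearly all macrophage genes with a clear signal would fall; of 18 such genes on a list written for this test, 11 (61.1%, exact 95% interval 35.7 to 82.7) had a difference of -0.5 or lower, 7 of the 12 that were on none of the earlier lists, which leaves fewer macrophages and lower expression of these genes in the epithelial cells open. The 2 with the highest signal, Cd14 (8.83 in Ccnd1+/+ cells) and Ptpn6 (8.78), differed by -0.30 and 0.06 without passing, and how many of these genes the epithelial cells express was not determined. A smaller share of every non-epithelial cell type alike would lower smooth muscle markers about as much as the macrophage genes. Smooth muscle markers with a clear signal had a median of -0.0806 (bootstrap 95% interval -0.30 to 0.06), above the bound set at -0.35. The macrophage genes had -0.70 (-0.83 to -0.26), and the intervals overlap. Both resample genes and not arrays, so they measure no spread between samples and the test cannot decide. Whether the smooth muscle transcripts came from smooth muscle cells is also not known. The 6 endothelial markers, at -0.19 (-0.92 to -0.06), decide nothing, while fibroblast markers, at -0.50, lay nearer to the macrophage genes.

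Dhcr7 and Nadsyn1, next to Ccnd1, were lower. DNA of another strain carried along with the targeted allele could change genes around it. Of the nearest 53 measured genes on chromosome 7 (50 before Ccnd1 and 3 after it, up to its end), 6 passed the threshold, 1 higher and 5 lower. Which of the other genes named above lie in this stretch is not given here. The share past the threshold was 11.3% (exact 95% interval 4.27 to 23.0), against 9.92% of other genes (Fisher's exact test, two-sided, p = 0.647). The interval includes double the share elsewhere, so a carried segment cannot be told apart from the background of changed genes with this few genes, and an effect of cyclin D1 on both genes was not tested.

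The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. Each of the other 9 divisions mixes the genotypes in both groups. The genotype difference then adds to the spread within groups, so their low counts of genes are no measure of chance. The real division gave the only count of genes above 0 in limma (1 of 10 divisions each for genes changed, higher, lower and at least 2-fold): 1804 genes, with 449 higher, 1355 lower and 158 at least 2-fold changed, against a highest of 0 in the others, which had 234 to 977 genes at an unadjusted p under 0.05 where the real one had 4700. For gene lists, 4 of the 10 divisions, the real one included, gave at least its 5 lists, and the highest of the others was 6.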

How the results depend on the processing

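The covariate from the control probe sets was chosen after seeing the data; the other alternatives were planned. Ccnd1 kept its direction and call under all 15 (-3.06 to -2.26). Counts of genes changed, genes higher, genes lower and genes changed at least 2-fold stayed within 1.5 times of 1804, 449, 1355 and 158 with the mean of probe sets, the filter, both normalizations, the other prior, array weights and the replicate block. Of the 1804 calls, however, the mean of probe sets kept 1268 (70.3%), with 45 genes of the other sign, and the block 1218 (67.5%). With every probe set tested on its own the counts were 3784, 1631, 2153 and 391, counting probe sets in place of genes. The covariate gave 252 changed, 85 higher and 167 lower, with 233 of the 1804 calls kept; the cause was not tested. Leaving out 1 array, which lowers the power, gave 692 to 1195 changed (880 without Ccnd1+/+ replicate 1, 692 without Ccnd1-/- replicate 1), 216 to 331 higher and 476 to 895 lower. The replicate block gave 1278 changed genes, 337 higher and 941 lower; same-numbered arrays correlated at -0.13, -0.08 and -0.26 in their deviations, so no array went best with its own number and the numbers do not pair the arrays.

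None of the 88 named genes past the threshold beside Ccnd1, nor of the 5 lists, changed sign; 53 genes passed in every leave-out and 28 under every alternative that kept them, since the filter removed the dimmest. Signs of the named genes and lists turned only where nothing had passed, and the cause was not tested. With the mean of probe sets, Fancf read 0.086, Nhej1 0.0106 and Mpg 0.0507. With every probe set tested on its own, the list means were 0.0315 for G1 cyclins, 0.0796 for end joining, 0.00717 for excision and mismatch repair and 0.0192 for the neighbours of Ccnd1. With the filter the luminal mean was 0.0061. With array weights Ccnd3 read 0.0579 and Cdk4 0.00804. With the covariate Tek read 0.102, Ccnd3 0.126 and Cdk4 0.324. Leaving out 1 array, Ccnd3 ran from -0.122 to 0.0459, Cdk4 from -0.183 to 0.0943 and the luminal mean from -0.0885 to 0.00531. No scaling moved the median of all genes by over 0.1. Without detection calls, signal over background was not measured here, so changes of dim genes are the least certain.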

Other observations

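The 7 lists in this part were written after the top genes and the counts of the first lists had been seen, and the test on chromosome 8 after the gene tests.

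Genes of Schwann cells and other glia were lower as a group in Ccnd1-/- cells. Of 22 measured, 11 fell and 0 rose (adjusted over the list alone, 17 and 0; mean -0.82, camera adjusted p = 1.33e-09; adjusted p = 0.051 with an estimated correlation). Sox10, the transcription factor gene of neural crest derivatives, fell from 6.67 ± 0.18 to 5.58 ± 0.12 (SD, n = 3), Nes, the gene of the intermediate filament nestin, by 0.80 and the adhesion gene L1cam by 0.62. Reln, Ngfr, Fabp7 and Cdh19 were already known to be among the largest falls when this list was written, so the list is not independent evidence of its direction, and Postn is also on the fibroblast list. Of 42 macrophage genes, 19 fell and 0 rose (list alone, 21 and 0; mean -0.41, adjusted p = 4.27e-06; adjusted p = 0.051 with an estimated correlation), with the Fc receptor gene Fcgr3 down by 1.48, Clec7a by 1.08 and Mpeg1 by 1.05; 11 of them are also on the earlier lists. Of 15 T and B lymphocyte genes, 0 fell or rose by either adjustment in limma (mean 0.03, adjusted p = 0.0676).

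Immediate early genes, which growth factors and handling switch on within minutes, were lower as a group: of 21, 6 fell and 0 rose (list alone, 12 and 0; mean -0.32, adjusted p = 0.000238; adjusted p = 0.051 with an estimated correlation). Fos fell from 9.06 ± 0.10 to 7.79 ± 0.15, Egr1 by 0.82 and Dusp1 by 0.47. Of 11 genes on the list of the aryl hydrocarbon receptor, a sensor of xenobiotics, 5 fell by either adjustment. Among them were Cyp1a1, from 7.21 ± 0.38 to 5.63 ± 0.17, and Cyp1b1, by 0.63. The list had a mean of -0.40 (camera adjusted p = 0.0203, and 0.1 with an estimated correlation). Beside targets it holds the receptor gene Ahr and the gene of its partner, Arnt, which did not pass. Of 11 noncoding RNAs listed as nuclear-retained, whose place in the cell was not measured here, 3 rose and 0 fell. Over the list alone the numbers were 3 and 4 (camera adjusted p = 0.0837). Malat1 rose from 11.55 ± 0.33 to 12.94 ± 0.12, Neat1 by 0.75 and Kcnq1ot1 by 1.68 in its brightest probe set. Meg3 read -0.60 without passing. The mean of this list was 0.25 and its median -0.04, and 1 of the other probe sets of Malat1 fell (-0.97). Of 20 ribosomal protein genes, 0 passed by either adjustment in limma (mean 0.01, adjusted p = 0.148).

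Along the chromosomes, the most genes past the threshold in any 50 neighbouring measured genes was 16. They lay on chromosome 8 between Gtf2e2 and Sorbs2, 13 lower and 3 higher. Over 1000 shuffles of the calls the median was 13 and the highest 19 (permutation p = 0.043, for the highest window of the genome). The shuffles treat neighbouring genes as independent. The p-value thus makes no allowance for neighbours that change together and measures no spread between samples.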
